A study of Cucumis sativus with 21 samples.

How the data were processed

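Total RNA from cucumber roots was hybridised to 21 Agilent 1-colour arrays, 3 for each of 7 groups. Per the labels' protocols, seedlings were held for 24 h in aerated nutrient solution. The control solution held 0.1 mM KH2PO4 as phosphorus source and 100 µM FeNaEDTA as iron source. In the phosphorus-omitted group KH2PO4 was left out, and in 2 further groups FePO4 was given in its place, as nanoparticles or as non-nano (bulk) powder. In the iron-omitted group FeNaEDTA was left out, and again 2 further groups received nano or bulk FePO4 in its place. The amount of FePO4 is not given in the sources used here. Each array held the pooled roots of 3 seedlings from a pot, and per the labels the whole experiment was carried out 3 independent times, which makes the replicates biological. Cy3-labelled cRNA was made from 200 ng RNA.

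Each deposited scanner file holds fluorescence intensity per spot on a linear scale, written by Agilent Feature Extraction 10.5.1.1, per the submitters' processing notes. The processed signal used here is the scanner software's background-subtracted intensity, per the file headers. An array carried 30338 non-control probes, each with its own transcript name, from 21588 loci; 16677 loci had 1 probe and the rest up to 60. A further deposited value table holds the same intensity values after a scaling by the authors. On every array its values equalled the processed signal times a constant, which brought the 75th percentile to between 3162 and 3163; its medians lay between 845.5 and 934.0, on a linear scale without centring. In 1 of the scanner files, that of replicate 1 of the nano FePO4 iron group, decimals are written with commas and processed signals are rounded to few digits.

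Probe names are transcript identifiers of the form Cucsa followed by numbers. None of them (0) matched the reference gene table, and the files pair them with no gene name or description. The gene lists fixed before the data were examined (iron and phosphate acquisition, stress, metabolism and cell type markers) could therefore not be matched to probes, and no list test was run. Probes are reported by identifier, with at most 2 higher and 2 lower per comparison.

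Control spots were left out. The log2 processed signal was taken relative to each array's 75th percentile. A probe was tested where it was well above background on all 3 arrays of at least 1 group, which kept 26938 probes from 18683 loci. Among these, 4259 spot values marked as outliers by the scanner software (0.753% of values) were left out, so the number of probes tested differs slightly between comparisons. No spot was marked as saturated (0 on every array). Group means and differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) over all 21 arrays, with a coefficient per group, 14 residual degrees of freedom and 3.65 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and a probe was called at an adjusted p below 0.05. A total of 14 comparisons was fixed beforehand, 13 between pairs of groups and 1 of the nano-minus-bulk difference between the iron and phosphorus arms. Named probes are the called probes with the largest log2 difference whose arrays do not overlap between the groups compared. Where nothing was called without a block, the same rule was applied to the calls made with the replicate as a block, a step added after the calls were seen. A level below the array's 75th percentile has a negative log2 value. Tables were prepared with Python 3.11.15 and pandas 2.3.3.

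Brightness limits what dim probes can show. The 75th percentile of the processed signal ran from 1670 on replicate 1 of the control to 5105 on replicate 2 of the nano FePO4 phosphorus group, and between 84.4% and 91.7% of probes were well above background. The number of arrays limits the precision: the median standard error of a difference between 2 groups was 0.23 on the log2 scale.

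The arrays came from 6 scanned slides on 4 scan days. The slide identifiers in the files occur on more than 1 scan, so a scan was taken as a slide. Slides 1 to 5 held 4 arrays each from 4 different groups, and slide 6 held only replicate 3 of the bulk FePO4 iron group. On slide 2 the 4 arrays had a compressed bright end, with the 99th percentile 3.64 to 3.82 log2 units above the 75th against 3.91 to 4.07 on the other 17 arrays, and 495 to 719 outlier spots against 33 to 437. Slide is therefore given as a block beside each comparison, and as differences within each slide that held both groups for named probes.

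Replicate numbers come from the sample titles. Deviations of same-numbered arrays from their group means were correlated across probes. In 8 of the 13 comparisons between groups every same-numbered pair had a correlation above 0.1, with the lowest at 0.11 and the highest at 0.62, and there the numbers were taken to pair the arrays. The 5 others were the comparisons with the control other than phosphorus omission. Replicate 2 of the control shared slide 2 with replicate 1 of 3 other groups. This rule judged each comparison by itself and not by the design. It pairs phosphorus omission with the control and with iron omission, but not iron omission with the control, where the pairs were at 0.51, 0.02 and 0.32. The count with the replicate block for that comparison is given with the dependence on processing. Replicates of a group correlated at 0.965 to 0.991 over probes, and no pair was near identical: the smallest median absolute difference was 0.181 log2 units.

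The fits were tested on simulated data: residuals of 24525 probes were mixed over arrays at random, and 200 probes were changed by known amounts. Over the 13 comparisons between groups, 42.1% to 56.4% of probes changed 2-fold were called, 84.5% to 93.4% of those changed 4-fold, and 96.4% to 98.8% of those changed 8-fold. Unchanged probes made up 5.1% of all calls, and between 0 and 20.4% in a comparison. Random mixing makes the comparisons alike in the simulation, and each had 5 draws. This range therefore shows the variation between draws and gives no rate for a particular comparison. For the set test, 4.8% of 400 random sets of 27 unchanged probes reached p below 0.05 in the simulated comparison of nano with bulk FePO4 as iron source. The simulation held no slide or replicate structure. Its detection rates hold for 200 changed probes, since with fewer changed probes the adjusted threshold is stricter. In the data, the fit without a block did not call Cucsa.121580.1, which was 5.23-fold higher in −P+nano than in −P. The rates therefore do not tell what share of real changes was called, and 0 calls do not exclude 4-fold changes.

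A total of 12 alternatives was fixed beforehand, besides leaving out each array in turn: quantile normalisation, normexp background correction (offset 50), the deposited values, no filter, a filter on all arrays, the replicate, slide or scan day as a block, only the arrays compared, an added threshold of 1 on the absolute log2 difference, an intensity trend with a robust prior, and array quality weights. For normexp the median spot signal was used, as no mean signal is among the columns of these files, and 15768 background values that the scanner software marked as outliers were replaced by the array's median background. After the data were examined 2 alternatives were added, the replicate block with array quality weights and a fit without the arrays of slide 2, as well as pooled comparisons and set tests (limma's fry).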

Results

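The root transcriptome of cucumber (Cucumis sativus) seedlings was profiled after 24 h of nutrient treatment, on 21 arrays in 7 groups of 3. The groups were a complete solution (control), phosphorus omission (−P), phosphorus omission with nano FePO4 (−P+nano) or bulk FePO4 (−P+bulk), iron omission (−Fe), and iron omission with nano FePO4 (−Fe+nano) or bulk FePO4 (−Fe+bulk). FePO4 is a sparingly soluble salt that contains both elements, and the comparisons ask how roots respond to lacking either nutrient and whether particle size changes the response to FePO4 as its source. Between 25615 and 27808 probes per array were well above background.

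**Figure D1:**
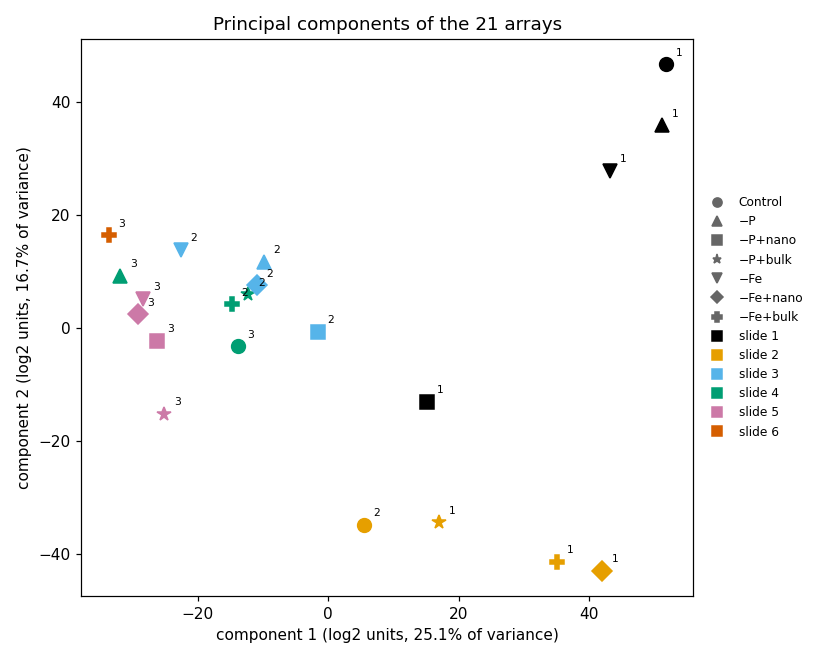
Principal components 1 and 2 (log2 units) of the 21 arrays over the tested probes with no value left out; symbols give the group, colours the slide, and the numbers the replicate. Component 1 holds 25.1% of the variance and component 2 holds 16.7%; replicate 1 arrays lie to the right, and on component 2 the 4 arrays of slide 2 lie lowest and 3 of the 4 arrays of slide 1 highest, with replicate 1 of −P+nano below 0.

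The largest differences between arrays did not follow the treatments. Group membership accounted for 5.4% of component 1, where 30% is the average under random labels, while the replicate number accounted for 87.7% and the slide for 87.1%. Each group held 1 array of each replicate number, so group could take only what the replicate number left. Random labels ignore this balance, so on component 1 the 30% does not show a group share below chance. For component 2 these shares were 26.7%, 0.9% and 77.7%. In permutation tests of 100000 draws, adjusted over 9 relations, the replicate number on component 1 had p = 9e-05, the smallest they can give, and the slide had p = 2e-04 on component 1 and 6e-04 on component 2. The permutation tests of group gave p = 1 and p = 0.9.

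In the fit without a block, iron omission lowered a small set of probes against the control. Cucsa.182020.1 fell by 3.27 on the log2 scale (SE 0.53, adjusted p = 0.0487), from −4.57 ± 0.42 in the control to −7.84 ± 0.98 in −Fe (SD, n = 3 arrays each, limma). Cucsa.184710.1 fell by 3.27 (SE 0.46, adjusted p = 0.0348), from 1.43 ± 0.15 to −1.84 ± 0.89, which is 9.62-fold lower. Of 26931 probes tested, 5 from 4 loci passed, all of them lower in −Fe. The other 3 were Cucsa.182040.1 and both transcripts of a further locus, and they fell by 1.20 to 2.63. Cucsa.182020.1 was well above background on 2 of the 3 −Fe arrays, and with normexp background correction its difference was −1.33 (adjusted p = 0.599). On slide 1, the slide that held both groups, the 2 named probes differed by −3.27 and −4.36. With slide as a block 2 probes passed, 1 higher and 1 lower, and both named probes had adjusted p = 0.0786. Array quality weights brought the count to 79, with 74 higher and 5 lower. Scan day as a block gave 12, with 6 higher and 6 lower. The calls with the replicate block, given with the dependence on processing, were mostly higher in −Fe. The direction of the calls thus depended on the fit, and the 5 lower probes do not show that iron omission mainly lowered expression. Each of the 6 arrays, when left out, brought the count to 2 or fewer, and to 0 for 5 of them.

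Phosphorus omission gave no called probe against the control. The limma test called 0 of 26929 probes, with 664 at an unadjusted p below 0.05 where 1346 would pass by chance alone. The number at that p was 1178 with the replicate block and 1112 with slide as a block. Without a block every comparison fell below its chance number, so 0 calls do not show that no probe changed. Of the probes lowered in −Fe, Cucsa.182020.1 was at −3.04 ± 0.29 in −P and Cucsa.184710.1 at 2.68 ± 0.23, above their control levels, though neither difference from the control passed the test. Both transcripts of the locus not named above lay below their control means in −P as well. A total of 195 probes (0.724%) differed by more than 2-fold in group means. The slide block and the replicate block also called 0 probes.

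**Figure D2:**
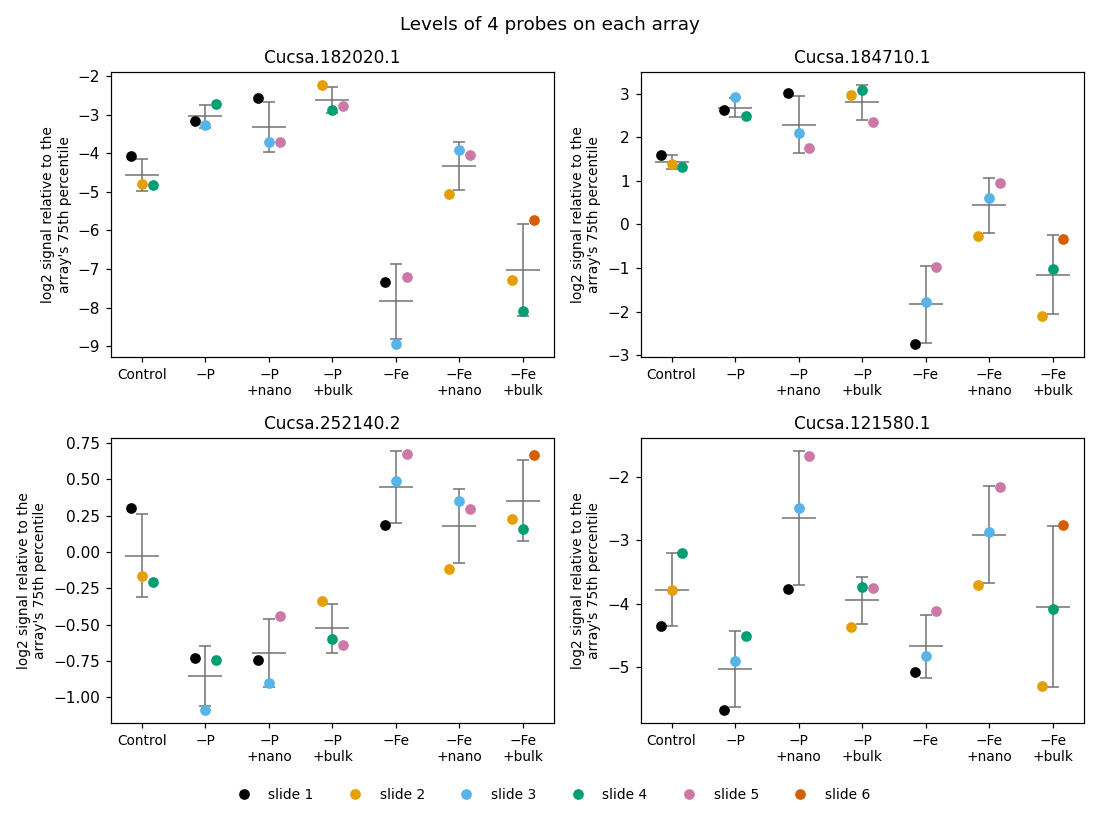
Log2 signal relative to the array's 75th percentile for 4 named probes; each point is an array, coloured by slide, and the bars give the group mean and SD (n = 3). Cucsa.182020.1 and Cucsa.184710.1 were low in −Fe and −Fe+bulk and highest in the 3 groups without KH2PO4, Cucsa.252140.2 was higher in the 3 groups without FeNaEDTA than in those without KH2PO4, and Cucsa.121580.1 had its highest means, −2.65 and −2.91, in the 2 nano groups.

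The responses to the 2 omissions differed most clearly when set against each other. Cucsa.182020.1 was 4.80 log2 units lower in −Fe than in −P (a difference of −4.80, SE 0.53, adjusted p = 0.000422) and Cucsa.184710.1 was 22.9-fold lower (log2 difference −4.52, SE 0.46, adjusted p = 0.00017). In the other direction, Cucsa.252140.2 was 2.47-fold higher in −Fe (log2 difference 1.30, SE 0.20, adjusted p = 0.0183), at 0.45 ± 0.25 against −0.85 ± 0.21 (n = 3). Its control mean of −0.025 was farther from −P than from −Fe, and without a block neither difference from the control was called. Cucsa.252140.2 had adjusted p = 0.0848 with slide as a block, and 1 of the 3 −Fe arrays was not well above background at Cucsa.182020.1, whose difference was −2.49 with normexp background correction (adjusted p = 0.00197). limma called 7 probes from 7 loci, 1 higher and 6 lower in −Fe. Within slides 1 and 3, which held both groups, Cucsa.182020.1 differed by −4.19 and −5.71, Cucsa.184710.1 by −5.38 and −4.70, and Cucsa.252140.2 by 0.91 and 1.58.

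With the replicate as a block, 27 probes from 24 loci passed between −Fe and −P, 16 higher and 11 lower in −Fe, and all 7 earlier calls were among them. The slide block called 13 probes, 8 higher and 5 lower. Relative to the control, the 16 higher probes had a mean log2 level of 1.41 ± 0.33 in −Fe (SD over 3 arrays) and −0.17 ± 0.20 in −P. The 11 lower probes were at −1.66 ± 0.09 in −Fe and 0.81 ± 0.24 in −P. Levels in −Fe and −P are those on which the probes were chosen. The arrays of the other groups entered that choice through the probes' spread and the block terms, not through their own group means. The 16 probes were at 1.07 ± 0.32 in −Fe+bulk, 0.70 ± 0.33 in −Fe+nano, −0.12 ± 0.17 in −P+nano and −0.01 ± 0.04 in −P+bulk. The 11 probes were at −1.23 ± 0.45 in −Fe+bulk, −0.19 ± 0.26 in −Fe+nano, 0.38 ± 0.09 in −P+nano and 0.74 ± 0.03 in −P+bulk. The count of 7 fell to 4 without replicate 2 of −P and to 3 without its replicate 3.

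**Figure D3:**
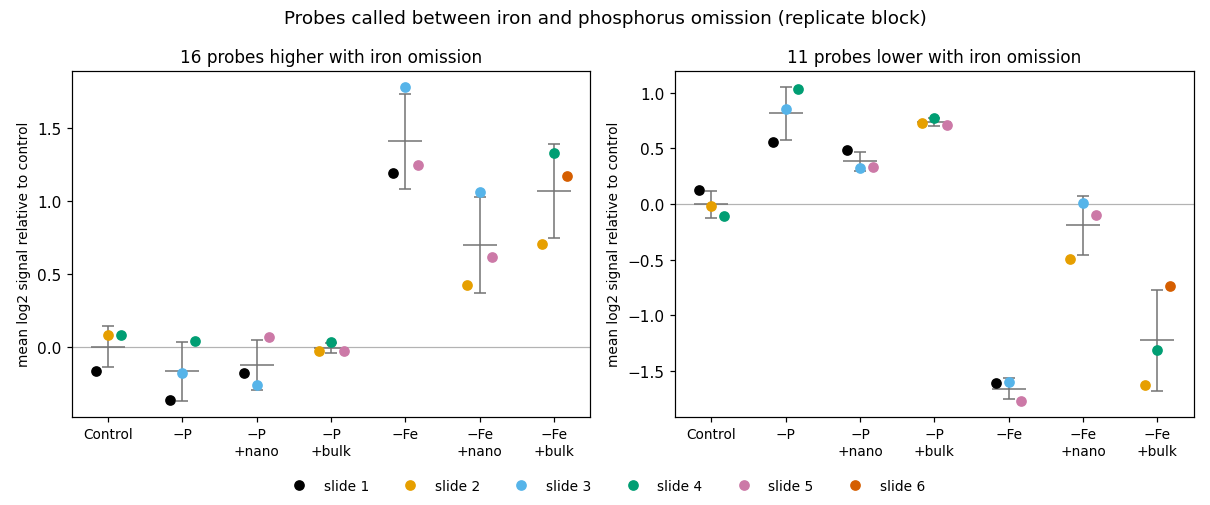
Mean log2 signal relative to the control of the 16 probes higher (left) and 11 probes lower (right) in −Fe than in −P with the replicate as a block; points are arrays coloured by slide, bars are the group mean and SD (n = 3). The 3 −Fe+bulk arrays lie on the side of −Fe in both panels, and the −Fe+nano mean is 0.70 on the left and −0.19 on the right.

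Nano FePO4 supplied to iron-omitted roots gave calls at 2 of the 5 probes called as lowered by iron omission, both higher than in −Fe. The same 3 −Fe arrays entered both comparisons, so low values on these arrays alone would give both the fall and the rise. Cucsa.184710.1, another of the 5, was not called here, with means of −1.84 in −Fe and 0.43 in −Fe+nano. Both transcripts of the unnamed locus among the 5 stayed near their −Fe means of −2.49 and −2.52. In −Fe+nano these transcripts were at −2.26 and −2.23, with control means of −1.23 and −1.32. Cucsa.182020.1 rose 11.4-fold from −Fe to −Fe+nano (log2 difference 3.51, SE 0.53, adjusted p = 0.0482) and reached −4.33 ± 0.62 (n = 3), close to its control mean of −4.57. Cucsa.182040.1 rose 6.99-fold (log2 difference 2.81, SE 0.39, adjusted p = 0.0368), from −7.10 ± 0.39 to −4.30 ± 0.37, with a control mean of −4.47. They were the 2 probes called by limma, among 26934, and both rose. Their means were also close to each other in −P (−3.04 and −3.14), −P+nano (−3.32 and −3.42) and −P+bulk (−2.62 and −2.74). Whether the 2 probes report separate transcripts was not tested. Within slides 3 and 5 the differences were 5.04 and 3.17 for Cucsa.182020.1 and 3.59 and 2.76 for Cucsa.182040.1. Each was well above background on 2 of the 3 −Fe arrays, and with normexp background correction the rises were 1.34 and 1.27, both with adjusted p = 1. Leaving out any of the 6 arrays left 0 or 1 call (1 without replicate 2 of −Fe, 0 without each of the others). With the replicate as a block 4 probes passed and with slide as a block 8, all of them higher in −Fe+nano. Array quality weights brought the count to 24, with 17 higher and 7 lower.

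Bulk FePO4 supplied to iron-omitted roots gave no called probe against iron omission. Cucsa.182020.1 stayed at −7.03 ± 1.20 and Cucsa.184710.1 at −1.15 ± 0.90 in −Fe+bulk (n = 3 each). limma called 0 of 26933 probes, with 295 at an unadjusted p below 0.05, and the slide block also called 0.

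When nano and bulk FePO4 were compared directly as iron source, limma called 0 of 26934 probes, with 579 at an unadjusted p below 0.05 and a smallest adjusted p of 0.312. Cucsa.184710.1 had a mean of 0.43 ± 0.62 with nano and −1.15 ± 0.90 with bulk FePO4. With slide as a block 3 probes passed, all higher with nano FePO4, and with the replicate as a block 0 passed. Calls for nano and not for bulk FePO4 against iron omission are thus not shown to differ between the materials by a probe-wise test without a block.

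Among phosphorus-omitted roots, nano FePO4 gave 0 called probes of 26929 by limma, with 574 at an unadjusted p below 0.05. Cucsa.121580.1, chosen from the fit with the replicate as a block, was 5.23-fold higher in −P+nano than in −P, with a log2 difference of 2.39. Its standard error was 0.27 and its adjusted p 0.00354 with the replicate block, against 0.59 and 1 without. It was the 1 probe called with the replicate block. With slide as a block it was also the count of 1, with an adjusted p of 0.00494. The differences within slides 1 and 3 were 1.91 and 2.41. Its level was −5.04 ± 0.60 in −P, −2.65 ± 1.06 in −P+nano, −3.95 ± 0.36 in −P+bulk and −3.78 ± 0.57 in the control.

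Bulk FePO4 in phosphorus-omitted roots gave 0 called probes of 26928 against −P, with 1326 at an unadjusted p below 0.05 in limma. With the replicate block 2095 were at that p, and 1288 with slide as a block, where 1346 would pass by chance alone. The excess with the replicate block was not tested, and 0 calls do not show that bulk FePO4 was without effect. Nano and bulk FePO4 as phosphorus source did not differ at any probe that passed, with 0 called of 26930 and 135 at an unadjusted p below 0.05. The slide block and the replicate block called 0 in both. Cucsa.182020.1 and Cucsa.184710.1 had similar means in −P+nano (−3.32 and 2.29) and −P+bulk (−2.62 and 2.80).

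Each FePO4 group was also set against the complete solution. By limma the called counts were 0 for all 4 groups, with 484 probes at an unadjusted p below 0.05 in −P+nano, 683 in −P+bulk, 563 in −Fe+nano and 758 in −Fe+bulk. The slide block called 1 probe, higher in −Fe+nano than in the control, and 0 in the 3 others. The nano-minus-bulk difference was compared between the iron and the phosphorus arms as an interaction. limma called 0 of 26926 probes without a block, with 226 at an unadjusted p below 0.05, and 3 with slide as a block, all with a larger nano-minus-bulk difference in the iron arm.

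**Figure D4:**
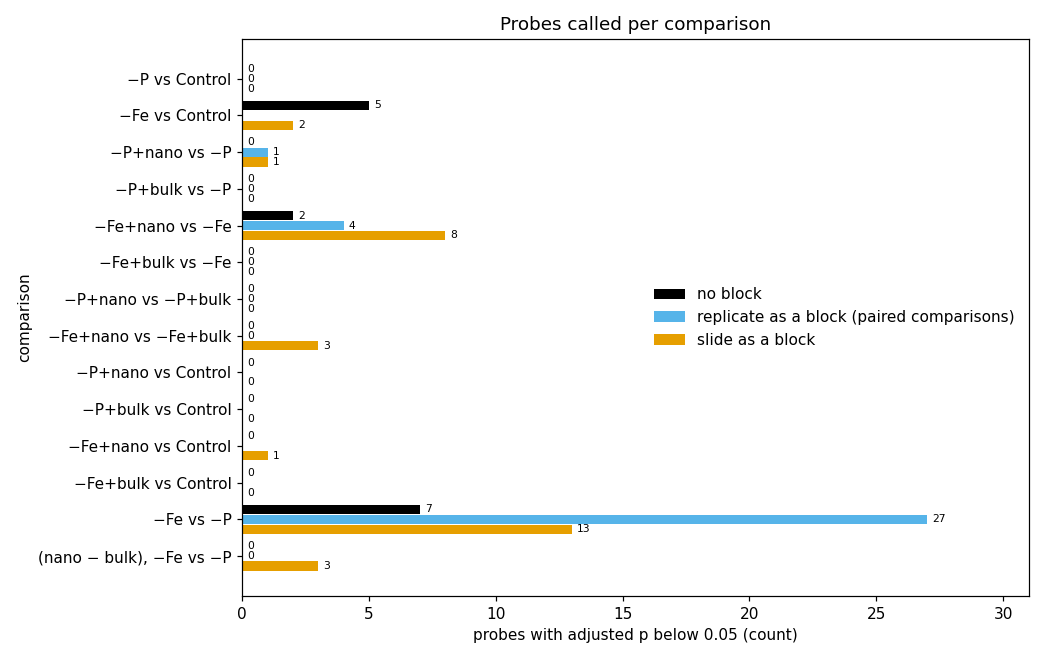
Number of probes with adjusted p below 0.05 (bar length, count) in each of the 14 comparisons, without a block, with the replicate as a block where the numbers pair the arrays, and with slide as a block. By each fit −Fe against −P has the largest count (7, 27 and 13), and comparisons of bulk FePO4 with the omission it was given in have 0 by each fit.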

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

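The test of the split of arrays in this part was chosen after the calls were seen. The effect of omitting iron and that of omitting phosphorus differed at 7 probes, by a direct test of −Fe against −P, which is the difference between the 2 omission effects since both are taken against the same control. The 2 named probes lower in −Fe differed by −4.80 (Cucsa.182020.1) and −4.52 (Cucsa.184710.1) and the named probe higher in −Fe by 1.30 (Cucsa.252140.2) on the log2 scale. The 6 arrays can be split in 10 ways, too few for a share under 0.05; the labelled split, 1 of the 10, gave 7 calls and the highest of the others gave 0. Weighing of what lies behind these probes is given with the other observations.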

How the results depend on the processing

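Alternatives added after the data were examined are the replicate block with array quality weights and the fit without the arrays of slide 2. The deposited values and the added log2 threshold kept all 14 counts within 1.5 times. For −Fe against the control (5 calls) the count was 1 with normexp, 0 without the filter, 1 with the filter on all arrays, 2 with slide as a block, 12 with scan day as a block (6 higher and 6 lower), 0 with only the arrays compared, 79 with array quality weights (74 higher and 5 lower), 0 with these weights and the replicate block, and 0 without slide 2. For −Fe+nano against −Fe (2 calls) it was 0 with normexp, 0 without the filter, 0 with the filter on all arrays, 0 with only the arrays compared, 8 with slide as a block, 24 with quality weights (17 higher and 7 lower), 75 with these and the replicate block (48 and 27), and 1 without slide 2. For −Fe against −P (7 calls) it was 12 with quantile normalisation, 11 with normexp, 13 with slide, 27 with scan day, 1 with only the arrays compared, 13 with the trend and robust prior, 160 with quality weights (124 higher and 36 lower) and 143 with these and the replicate block (42 of them lower). Among the comparisons with 0 calls, slide as a block gave 1 for −P+nano against −P, 3 for −Fe+nano against −Fe+bulk, 1 for −Fe+nano against the control and 3 for the interaction. Quality weights gave 1, 3, 7 and 2 in the same order. With the replicate block added they gave 5, 3 and 3 for the nano against −P, nano against bulk iron and interaction comparisons. Scan day gave 1 for −P+nano against the control, and the fit without slide 2 gave 1 for −P+bulk against −P. The fits with only the arrays compared estimate the spread from fewer arrays; for the other settings the cause was not tested.

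With the replicate as a block the pairing changed the counts to 27 for −Fe against −P, 4 for −Fe+nano against −Fe and 1 for −P+nano against −P, and changed no other call where numbers pair the arrays. For −Fe against the control, where no label says that a number marks the same run in both groups (lowest correlation of a pair 0.02), the block gave 19 calls, 14 higher and 5 lower, including the 5 made without it; in the other 4 comparisons with the control that the numbers do not pair it gave 0, with lowest correlations from −0.43 to −0.13. Leaving out each array in turn gave 0 to 2 calls for −Fe against the control, 0 to 1 for −P against the control (1 without replicate 2 of −P), 0 to 1 for −Fe+nano against −Fe, 0 to 2 for −Fe+nano against −Fe+bulk (2 without replicate 3 of −Fe+bulk), 3 to 8 for −Fe against −P, and 0 to 0 in the other 9. No named probe changed direction under any alternative run. Dim probes depend on the background step: with normexp Cucsa.182020.1 differed by −1.33 in −Fe against the control, by −2.49 in −Fe against −P and by 1.34 in −Fe+nano against −Fe, and Cucsa.182040.1 by 1.27 there. The planned shifts of gene lists were not run, since probe names could not be matched to the lists.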

Other observations

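The pooled comparisons and the sets of probes in this part were chosen after the data were examined, as was the test of nano against bulk FePO4 on the probes that separate the omissions; the tests with sets chosen apart came last. Apart from the direct tests of the highest against the lowest set, the tests with slide as a block and the test across arms were fixed before their results were seen. The adjustment of the set tests' p over their family came after these results, and each unadjusted p is smaller or equal. When the 3 groups without FeNaEDTA were set against the 3 without KH2PO4, limma called 34 probes (21 higher and 13 lower), 75 with the replicate block (53 and 22) and 57 with slide as a block (36 and 21). Of the 75, all 75 had the same direction with slide as a block and 49 passed there. Both nano groups against both omission groups gave 0 calls without a block (963 at an unadjusted p below 0.05), 10 with the replicate block and 4 with the slide block, all higher with nano FePO4. The 10 probes were 0.89 to 2.08 log2 units higher, and the 4 were among them. Both bulk groups against both omission groups gave 0 in each of the 3 fits, with 1442, 2205 and 1310 probes at an unadjusted p below 0.05. Set directly against each other, both nano and both bulk groups gave 0 calls without a block, 0 with the replicate block and 1 with slide as a block.

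The 27 probes that separate −Fe from −P lay on the −Fe side of the control with bulk FePO4 as iron source. Signed by their direction in −Fe, all 27 lay on the −Fe side of the control in −Fe+bulk, by 1.14 log2 units on average without a block (limma's fry, adjusted p = 9.29e-07 over 18 set tests), and 22 of 27 did in −Fe+nano, by 0.50 (adjusted p = 0.000311). With slide as a block these means were 1.13 (adjusted p = 0.000163) and 0.41 (adjusted p = 0.00434). Chosen by the difference between the omissions, the set can hold responses to either. In −P+bulk its 11 lower probes lay 0.74 above the control without a block (fry, adjusted p = 0.00614) and 0.89 with slide as a block (adjusted p = 0.0149). Its 16 higher probes lay at −0.01 there without a block (adjusted p = 0.898). With the replicate block nano minus bulk was −0.64 on average, lower for 24 of 27 probes. The FePO4 arrays entered the choice of probes through the spread and block terms of the fit over all 21 arrays. Another set of 27 probes was chosen from the −Fe and −P arrays alone, and 10 of these are among the first 27. In a fit of the nano and bulk arrays alone, nano minus bulk of this other set was −0.69, lower for 26 of 27 probes. That difference did not pass the test (fry, adjusted p = 0.0695). The other set tests used the 25 of the first 27 probes with no value left out. Fitted with the replicate block, the set test gave adjusted p = 0.00298, and leaving out each of the 6 arrays gave adjusted p from 0.00358 to 0.00889. If the placing of nano and bulk arrays on different slides were the cause, the difference should end with slide as a block. It stayed at −0.72 with adjusted p = 0.0159, which argues against slide layout as the whole cause. This argument is limited, since only slide 2 held both groups and replicate 3 of −Fe+bulk was alone on slide 6. The fit with slide as a block therefore rests largely on links through other groups. The difference came more clearly from the 11 lower probes (mean 1.04, adjusted p = 0.00507) than from the 16 higher ones (mean −0.37, adjusted p = 0.11). The difference between these subsets was not tested. The 11 lower probes did not move alike: 9 were higher with nano than with bulk FePO4 and 2 were lower. Cucsa.182020.1 was at −4.33 in −Fe+nano and −7.03 in −Fe+bulk, and Cucsa.184710.1 at 0.43 and −1.15. Both transcripts of the unnamed locus lowered in −Fe were at −2.26 and −2.23 in −Fe+nano. In −Fe+bulk they were at −2.18 and −2.14. The mean of 1.04 therefore does not describe an even shift of the 11 probes. A candidate explanation is that nano FePO4 relieved iron omission further than bulk FePO4 did within 24 h; a different amount of FePO4 in solution between the materials stays open and was not measured on these arrays.

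The 50 probes highest with nano FePO4 against the mean of −P and −P+bulk were then followed in the iron arm. Their mean in −Fe+nano against the mean of −Fe and −Fe+bulk was 0.58 log2 units, above 0 for 40 of 50 probes, with adjusted p = 0.00013 over 4 set tests in the fit with the replicate block. Leaving out each of the 9 arrays of the iron arm gave adjusted p from 0.000157 to 0.00041. With slide as a block in both steps the mean was 0.58, above 0 for 45 of 50, with adjusted p = 0.000296, which argues against the slide layout of the nano arrays as the whole cause. The 50 probes lowest with nano FePO4 in the phosphorus arm had a mean of 0.35 there, above 0 for 32 of 50, which did not pass the test (adjusted p = 0.0915). With sets chosen from the arrays of the phosphorus arm alone and tested in a fit of the iron arm alone, the highest had a mean of 0.41 (above 0 for 34 of 50, adjusted p = 0.0103) and the lowest of 0.42 (29 of 50, adjusted p = 0.144). None of the 50 highest (0) is among the 27 probes that separate the omissions. In direct tests of both sets (fry, 100 probes, the lowest set with its sign reversed), the signed mean was 0.12 with the replicate block (adjusted p = 0.0117). With slide as a block it was 0.11 (adjusted p = 0.0132), and with sets chosen apart −0.007 (adjusted p = 0.0695). Whether nano FePO4 raised a set of probes shared by the arms therefore stays open, since these direct tests disagree. With sets chosen apart the 2 means were alike, though the mean of the lowest set did not pass its test. No group with nano FePO4 in complete solution is among the 7.

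Other splits of the 6 arrays compared were counted for each comparison of 2 groups, 10 splits each, too few for a share under 0.05. For −Fe against the control the labelled split gave 5 calls and the highest of the others 1. For −Fe+nano against −Fe it gave 2, with 0 as the highest of the others, so that the splits that part as many pairs also gave 0. Where the labelled count is 0 every split reaches it, so these counts test nothing. In the 10 comparisons with 0 calls, all 10 splits gave at least as many, and the highest of the others was 2 for −P+nano against the control, 1 for −P and −Fe+nano against the control, and 0 elsewhere. For the interaction, all of 100 regroupings drawn gave at least the 0 calls of the labelled grouping, and the highest gave 0.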
